A study of Mus musculus with 2 samples.

How the data were processed

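RNA of peritoneal macrophages was sequenced on the BGISEQ-500 platform, per the labels' protocols, after co-culture with EO771 cells for 4 days. The labels give 1 wild type and 1 Lgmn knockout sample, and samples were grouped by their genotype label. The deposited files hold estimated counts and FPKM per Entrez gene, per the file headers, in the layout of RSEM. The estimated counts are not scaled between libraries. FPKM, made by the authors, is scaled to transcript length and to the fragments mapped in each library, per the file headers' unit name. HISAT2, Bowtie2, RSEM and the mm10 build are named in the submitters' processing notes, without roles or versions. The lowest FPKM in either file is 0.01, so a gene missing from a file lay below the authors' limit or was not counted. It was treated as a gene without counts in that file, so it enters the numbers of higher and lower genes. No fold is printed for it. Strand handling is not given in the sources used here, so overlapping and antisense genes cannot be told apart, and RSEM divides reads among similar copies by an estimate.

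The files list 15605 genes between them, 13832 in both, 849 only in the wild type file and 924 only in the knockout file. Symbols and coordinates came from a RefSeq table of GRCm38.p6, the same assembly as mm10, which matched 15561 of the gene identifiers. Estimated counts were rounded to whole numbers and scaled with TMM factors from edgeR 4.0.16 in R 4.3.3, 0.921 for wild type and 1.09 for knockout. Log2 ratios of knockout over wild type were taken after adding 1 scaled count to both libraries. Genes with at least 50 estimated counts in the higher library were tested for size, with 2-fold as the threshold. Intervals of a ratio are 95% exact Clopper-Pearson intervals of the knockout share of the counts. They cover counting error only, since reads without molecular identifiers are not independent molecules, and they say nothing of variation between mice. No test across samples was possible with 1 library per group. Depth was alike, at 11885784 and 11740202 estimated counts.

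The design, the alternatives, 51 gene lists with Lgmn alone as 1 of them and the rule for named genes were fixed before the data were examined. The rule takes Lgmn, the 12 genes with the largest positive and the 12 with the largest negative log2 ratio after adding 10 scaled counts, the 3 members of each list with the largest ratios, and the 5 most abundant genes of each library. Some genes that the rule takes are not reported here. Clone, numbered, histone and antigen receptor segment names were left out of the 12 genes. A list's median was placed among 10000 random lists of the same size, drawn from 20 bins of mean expression. A percentile describes these 2 libraries and is not a p-value. Lists with fewer than 5 members tested have values only, and a list was set apart at percentiles below 2.5 or above 97.5, bounds chosen after the values were seen.

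The alternatives run were DESeq2 1.42.0 size factors, library totals, FPKM as deposited with 0.1 added, median centring, minimums of 10, 200 or no counts, pseudocounts of 0.5 and 5, the deeper library thinned to the total of the other, and thresholds of 1.5-fold and 4-fold. After the data were seen, a lowess trend of the log2 ratio on log2 transcript length, with a span of 0.3, was subtracted, and random lists were also matched on length. Epcam, Krt8, Krt18, Fam177a2, Evi2, Tgtp2, Ifng, the granzymes and the sums over similar copies were chosen after their values were seen. GC content was the mean over a gene's RefSeq transcripts in GENCODE vM21, available for 99.3% of the genes tested.

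The procedure was tested on simulated data, drawn for both libraries from their mean counts with 200 genes changed 3-fold or 4-fold. Of 9296 genes tested there, all 100 raised and all 100 lowered genes passed 2-fold at either size, and 0 of 9096 unchanged genes did. The simulated counts held counting error only, with no length trend and no variation between mice or library preparations. Only genes with a mean of at least 100 counts were changed. This checks the calculation and does not measure how many genes pass 2-fold without a genotype difference in real libraries. Of 100 lists drawn at random from the simulated genes, changed genes included, 3 fell outside the central 95% of their random lists. Few are due outside by construction, so this checks the percentile calculation only. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.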

Results

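RNA was measured in peritoneal macrophages, the resident phagocytes of the abdominal cavity, taken from C57BL/6 mice that were wild type or lacked Lgmn. Lgmn encodes legumain, a lysosomal cysteine protease that cleaves after asparagine residues. The cells had been kept for 4 days with EO771 cells, a mouse mammary carcinoma line of C57BL/6 origin. Whether a membrane kept the cells apart is not given in the sources used here, so the RNA may include that of carcinoma or stromal cells, and ratios of matrix, fibroblast and keratin genes cannot be assigned to macrophages. There was 1 wild type library and 1 Lgmn knockout library, so no difference had a replicate check and no p-value was computed. The wild type library held 11885784 estimated counts over 14681 listed genes, and the knockout library 11740202 over 14756. The comparison asks which transcripts of co-cultured macrophages differ with the loss of Lgmn. The terms higher and lower describe these 2 libraries. A ratio is the knockout value over the wild type value after scaling, and its 95% interval covers counting error only.

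Lgmn (Entrez gene 19141, chromosome 12, 102394082 to 102439728 in GRCm38) was 64.3-fold lower in the knockout library, with an interval of 58.6 to 71.1. It had 23550 estimated counts and an FPKM of 1048 in the wild type library, and 426 counts and an FPKM of 19.2 in the knockout library. The counts cover the whole gene, and which exons were deleted is not given in the sources used here. The order of the libraries matches their genotype labels.

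Of 9498 genes with at least 50 estimated counts in the higher library, 575 were at least 2-fold higher and 165 at least 2-fold lower in the knockout library. The higher genes made up 77.7% of these. Scaling by library totals gave 1036 higher and 107 lower, a higher share of 90.6%. Deposited FPKM gave 936 and 102, a higher share of 90.2%. The log2 ratio followed transcript length. With the genes split into 10 groups by length, its median was -0.37 in the group of shortest transcripts and 0.77 in that of the longest, with a Spearman rho of 0.609 across genes, which are not independent replicates. The group of longest transcripts held 309 of the 575 higher genes. With this trend removed, 203 genes were at least 2-fold higher and 180 at least 2-fold lower, of which 177 and 114 were also counted without the adjustment. Length-adjusted values are given beside many of the results.

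**Figure D1:**
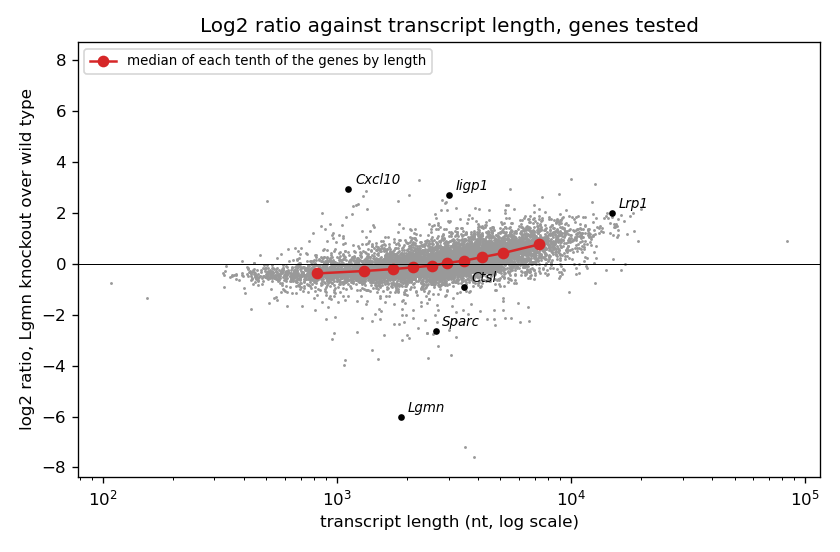
Log2 ratio of knockout over wild type against transcript length in nucleotides on a log axis, 1 grey point per gene tested, with the median of each of 10 groups of genes by length in red. The medians run from -0.37 to 0.77, while Lgmn lies at -6.01 and Cxcl10 at 2.95.

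Genes of the extracellular matrix and of contractile, fibroblast-like cells were lower in the knockout library. Of 15 extracellular matrix genes tested, 12 were at least 2-fold lower, 3 lay between and 0 were higher, with a median log2 ratio of -2.13. Of 13 fibroblast marker genes, 11 were at least 2-fold lower and 0 higher, with a median of -2.13. The lists share 11 members, 5 of them tested. Both medians lay below those of all 10000 random lists matched on expression, at a percentile of 0, and length adjustment put them at -2.57 and -2.48, with 14 and 11 genes at least 2-fold lower. Ccn1 and Ccn2, matricellular proteins, were 7.53-fold (5.45 to 11.2) and 6.58-fold (5.19 to 8.65) lower. Bgn, the proteoglycan biglycan, was 6.55-fold lower (5.21 to 8.53), and Sparc, a collagen-binding glycoprotein, 6.19-fold lower (5.35 to 7.25, from 1104 to 207 counts). The smooth muscle and myofibroblast genes Tagln and Acta2 were 7.02-fold (5.82 to 8.66) and 6.79-fold (5.55 to 8.51) lower. Myl9, of the same kind, had 83 and 6 counts, 13.8-fold lower (7.10 to 45.2), and its log2 ratio of -3.79 was -3.16 with a pseudocount of 5. Des, which encodes the muscle intermediate filament desmin, was 11.8-fold lower (7.77 to 21.1), and Serpinf1, which encodes pigment epithelium-derived factor, 13.4-fold lower (8.72 to 24.3). Des and Serpinf1 belong to neither list and were named because they were among the 12 lowest genes.

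Some regulators of matrix breakdown and some secreted growth factors were at least 2-fold lower too, while most genes of both lists lay between. Of 20 matrix proteases and inhibitors, 4 were at least 2-fold lower and 0 higher, with a median of -0.41 at percentile 0.40. Timp1 and Timp3, inhibitors of metalloproteinases, were 4.44-fold and 4.45-fold lower. Of 29 genes for factors linked to tumour-associated macrophages and angiogenesis, 7 were at least 2-fold lower and 0 higher, with a median of -0.42 at percentile 0.020. Pgf, placental growth factor, was 10.5-fold lower (5.87 to 26.3), from 90 to 9 counts, and its log2 ratio of -3.39 was -2.80 with deposited FPKM. Osm and Gdf15, both secreted cytokines, were 2.73-fold and 2.65-fold lower. The percentiles of these lists were 7.65 for the growth factors and 2.82 for the protease list when a gene needed 200 counts.

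**Figure D2:**
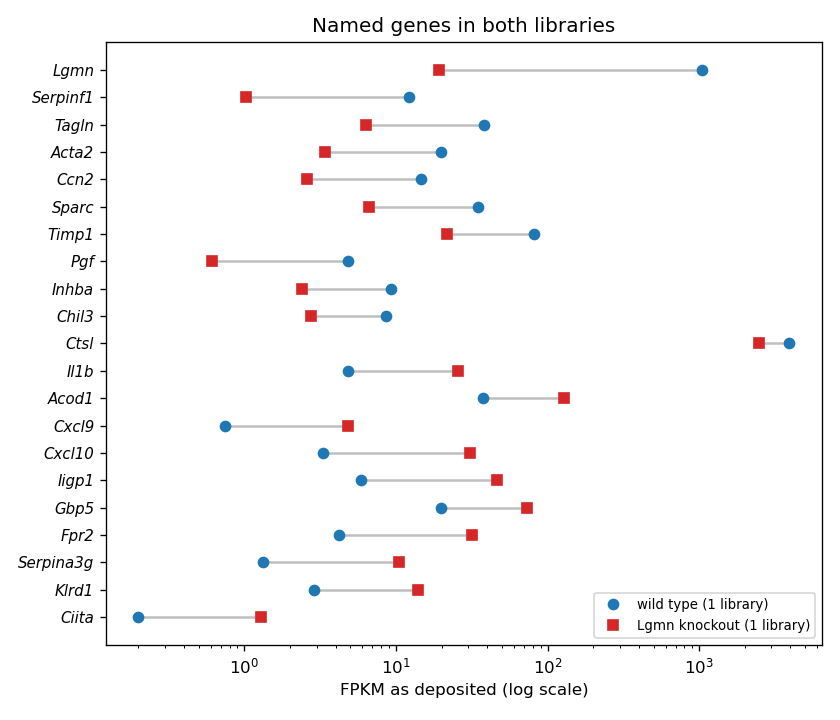
FPKM as deposited, on a log axis, of selected genes in the wild type library (circles) and the Lgmn knockout library (squares), 1 library each, with a line joining both values of a gene. Lgmn stands at 1048 and 19.2, Sparc at 34.7 and 6.59, and Cxcl10 at 3.32 and 31.0.

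A few genes of the interferon-stimulated list were higher in the knockout library by several fold, while most of the list lay between. The interferon-inducible GTPases, a family chosen after the values were seen, are described further below. Of 49 interferon-stimulated genes tested, 5 were at least 2-fold higher, 1 was at least 2-fold lower and 43 lay between, and 21 had a ratio below 0. Their median of 0.17 was above all matched random lists, at a percentile of 100. After length adjustment it was 0.07, at percentile 99.995, with 5 genes higher and 0 lower. Among random lists matched on length too, the percentile was 100. Cxcl10, a chemokine that attracts activated T cells, was 7.75-fold higher (5.78 to 11.04), from 44 to 405 counts. Iigp1, an interferon-inducible GTPase, was 6.50-fold higher (5.65 to 7.55), and Gbp5, a guanylate-binding protein, 3.13-fold higher (2.88 to 3.40). Tgtp1, which is not in this list, was 5.76-fold higher, but it shares sequence with Tgtp2, and their summed counts were 2.31-fold higher. Socs1, an inhibitor of cytokine signalling, was 5.16-fold higher (3.71 to 7.67). It belongs to the alternative activation list and not to this one.

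Genes of antigen presentation, inflammation and chemokines also contained higher members. Over all genes tested, 575 of 9498 were at least 2-fold higher, so single members past 2-fold do not set a list apart. Ciita, the transactivator of MHC class II genes, was 4.93-fold higher (2.88 to 10.2), and 1 of 8 MHC class II presentation genes passed 2-fold. Their median was 0.31 at percentile 99.8, and 0.56 after length adjustment, with 2 genes past 2-fold. Cd74, the MHC class II invariant chain, had a log2 ratio of 0.77, and of 1.03 after adjustment, and H2-Ab1 one of 0.47. Of 21 MHC class I presentation genes, 1 passed 2-fold, Nlrc5, their transactivator, at 3.53-fold higher (2.86 to 4.46), a log2 ratio of 1.82 that was 1.13 after length adjustment. The list median was 0.02, and 0.20 after adjustment. Of 23 inflammatory cytokines and enzymes, 5 were at least 2-fold higher and 2 lower. Il1b, a pyrogenic cytokine, was 4.46-fold higher (3.52 to 5.82) and Acod1, which makes itaconate, 2.91-fold higher (2.72 to 3.11). Inhba, which encodes an activin subunit, was 4.52-fold lower (3.28 to 6.60). The list median was 0.24 at percentile 97.8, and 0.30 after length adjustment. Of 17 chemokines, 4 were at least 2-fold higher and 3 lower, and 5 and 1 after length adjustment, which took their median from 0.21 to 0.59. Cxcl9 was 5.32-fold higher (3.61 to 8.63) and Cxcl13 3.88-fold higher (2.43 to 6.99). Fpr1 and Fpr2, receptors for formyl peptides, were 7.32-fold and 6.33-fold higher, and their summed counts 6.62-fold higher.

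Genes used to mark alternative activation went both ways. Of 14 tested, 3 were at least 2-fold higher and 2 at least 2-fold lower, and 2 and 1 after length adjustment, with a median of 0.22 at percentile 95.9. The median was -0.12 after length adjustment, -0.18 with a minimum of 10 counts and -0.32 with none, so its sign depended on these settings. The percentile was 99.57 with a minimum of 200 counts and 1.75 with no minimum. Chil3, a chitinase-like protein, was 3.65-fold lower (2.68 to 5.20), while Tgm2, a transglutaminase, was 2.39-fold higher (2.25 to 2.54). Socs1, described above, is another of the higher genes of this list.

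Several innate receptors were higher, and none of the toll-like, nucleic acid, scavenger or efferocytosis receptors tested was at least 2-fold lower. Of 22 toll-like and nucleic acid receptors, 4 were at least 2-fold higher and 0 lower, with a median of 0.49 at percentile 99.99. After length adjustment the median was 0.33 and 2 genes passed 2-fold. Tlr2, a receptor for bacterial lipoproteins, was 2.59-fold higher (2.20 to 3.07), and Nod1, a cytosolic peptidoglycan sensor, 2.75-fold higher (2.04 to 3.83). Of 21 scavenger and efferocytosis receptors, 4 were at least 2-fold higher and 0 lower, and 1 passed 2-fold after length adjustment. Mertk, a receptor for dying cells, had a log2 ratio of 1.23 and of 1.08 after adjustment. Lrp1, whose transcript is among the longest, had 1.99 and 0.58. Abca1, a cholesterol exporter with a long transcript, had 1.78 and 0.72. Among 28 chemokine and cytokine receptors, 1 was at least 2-fold higher, Ccr2 at 3.06-fold (2.04 to 4.93), and 2 were at least 2-fold lower. After length adjustment 1 was lower, and the percentile went from 99.95 to 92.5, but it was 98.9 among random lists matched on length too. Of 25 Fc receptor and complement genes, 1 was at least 2-fold higher and 0 lower, with a median of 0.12.

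Lysosomal genes other than Lgmn differed by less. Of 19 lysosomal proteases, 1 was at least 2-fold higher, 0 were lower and 18 lay between, with a median of -0.38 at percentile 6.46. After length adjustment 1 was higher and 1 lower, and the median was -0.25, at percentile 1.63. Ctsl, which encodes cathepsin L, had 167371 counts in the wild type library and 103507 in the knockout library, 1.88-fold lower (1.87 to 1.90). Its log2 ratio was -0.91, and -1.06 after length adjustment, -0.68 with library totals and -0.67 with deposited FPKM. Ctsw, a cathepsin of cytotoxic lymphocytes, was 2.73-fold higher (1.73 to 4.68). Of 45 lysosomal hydrolases and membrane proteins, 0 passed 2-fold in either direction, with a median of -0.24 at percentile 55.3, at percentile 0.40 after length adjustment and at 2.21 among random lists matched on length too. With deposited FPKM this median was 0.0039. None of 25 autophagy genes passed 2-fold, and their median of -0.18 was above 0 under scaling by totals.

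Of 21 genes of the integrated stress response, 4 were at least 2-fold lower and 0 higher, with a median of -0.46 at percentile 0. After length adjustment 3 were lower, with a median of -0.37. Asns, asparagine synthetase, was 4.85-fold lower (3.29 to 7.83). The 51 ribosomal protein genes had a median of -0.46 and the 56 oxidative phosphorylation genes one of -0.35, and 0 genes of either list passed 2-fold. Their medians were -0.08 and -0.04 after length adjustment. Length adjustment took the percentile of the ribosomal list from 0.070 to 76.1 and that of oxidative phosphorylation from 0.50 to 96.96. Among random lists matched on length too, they were 0.46 and 66.8. The place of the ribosomal list thus depended on how length was taken into account. Cell cycle lists showed 0 genes beyond 2-fold among 23 DNA replication and 17 mitosis genes, with medians of 0.01 and -0.01. After length adjustment 1 mitosis gene was lower and the DNA replication median was -0.03. The mitosis median was above 0 with totals, FPKM, thinning and a minimum of 200 counts. Its percentile of 19.0 was 0 with a minimum of 10 counts and with none, when more of its 45 members entered, so the list then lay below all matched random lists. None of 21 cholesterol synthesis genes passed 2-fold, and 2 of 25 lipid efflux and storage genes were higher, and 1 after length adjustment. Of 36 glycolysis and hypoxia genes, 2 were at least 2-fold lower and 0 higher. After length adjustment 0 passed 2-fold, while the percentile of the list went from 55.9 to 0.74, but it was 13.5 among random lists matched on length too. Of 29 NRF2 and oxidative stress genes, 3 were higher and 1 lower, and 2 and 2 after length adjustment. Heat shock and immediate early genes numbered 24, with 1 higher and 2 lower, and 2 and 1 after length adjustment, and 1 of 18 p53 targets was lower. None of 25 unfolded protein response genes passed 2-fold.

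**Figure D3:**
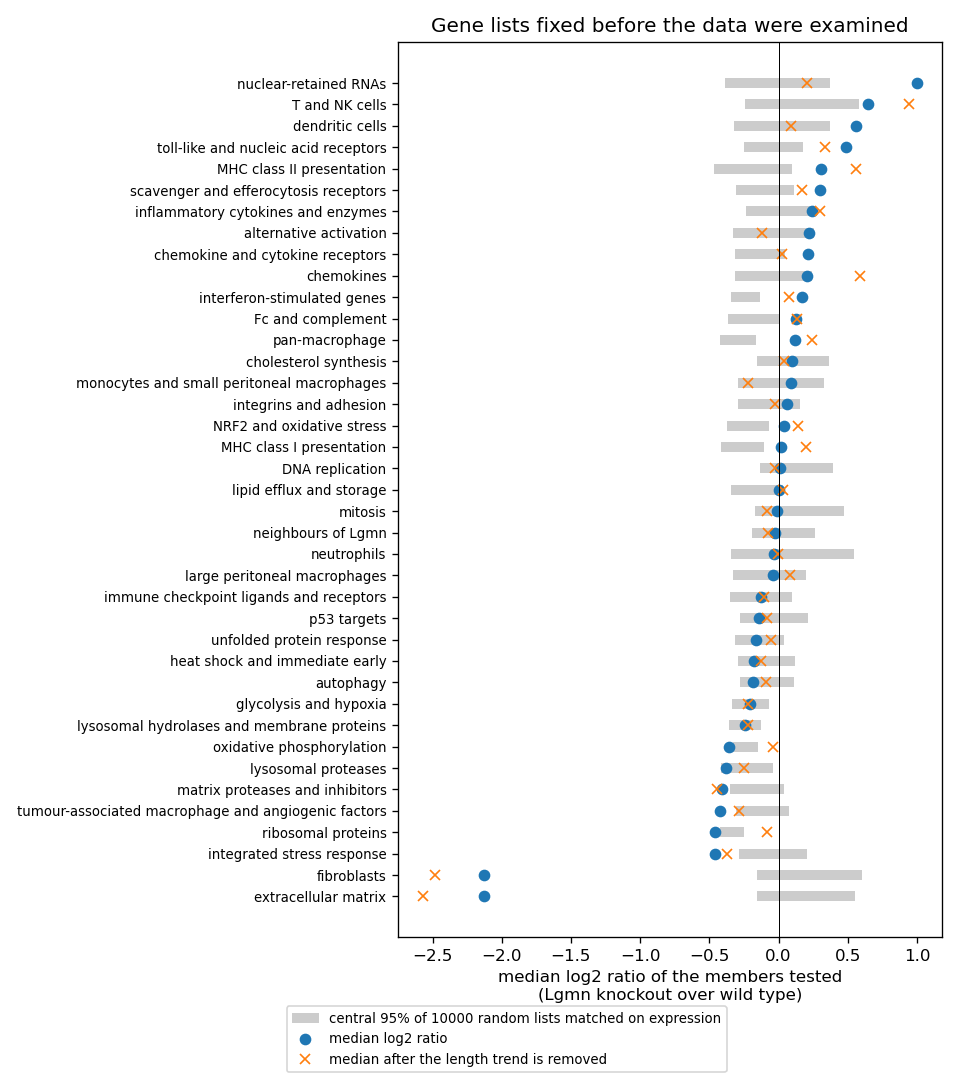
Median log2 ratio of knockout over wild type for 39 gene lists with at least 5 members tested (circles) and the same median after the length trend is removed (crosses), with grey bars for the central 95% of random lists. Extracellular matrix and fibroblast lists stand apart at -2.13, and T and NK cells lie at 0.65 and at 0.94 after adjustment.

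Markers of other cell types differed between the libraries alongside these groups. Of 13 T and NK cell markers, 5 were at least 2-fold higher and 0 lower, with a median of 0.65 at percentile 98.7. Klrd1 and Klrb1c, receptors of natural killer cells, were 4.02-fold (2.74 to 6.37) and 3.88-fold (2.53 to 6.56) higher. Of 11 dendritic cell markers, 3 were at least 2-fold higher and 2 lower, and 1 and 1 after length adjustment. Their percentile of 99.7 was 82.1 after adjustment and 99.4 among random lists matched on length too. Clec9a, a marker of cross-presenting dendritic cells, was 4.62-fold higher (2.69 to 9.60), from 13 to 74 counts. Among 26 pan-macrophage genes, 2 were at least 2-fold higher and 0 lower, with a median of 0.12 at percentile 100, and of 0.24 after length adjustment. Of 40 epithelial carcinoma markers 1 could be tested, the keratin gene Krt19, also in the mesothelial list, at 67 and 4 counts. Its log2 ratio of -3.96 was -3.34 with deposited FPKM and -3.15 with a pseudocount of 5. Epcam, Krt8 and Krt18 had at most 5 counts in either library. Of 19 markers of large peritoneal macrophages 2 were higher and 2 lower, and 1 and 2 after length adjustment. Of 14 markers of monocytes and small peritoneal macrophages 1 was higher and 2 lower, and 1 and 1 after adjustment, which took their median from 0.09 to -0.22 and their percentile from 76.5 to 2.06, against 89.5 among random lists matched on length too. None of 6 neutrophil markers passed 2-fold. Integrin and adhesion genes numbered 23, with 4 higher and 2 lower. After length adjustment 2 were higher and 1 lower, and their median went from 0.06 to -0.03. Of 19 immune checkpoint genes 1 was higher, and 0 after adjustment. Of 24 genes tested near Lgmn on chromosome 12, 4 were at least 2-fold higher and 0 lower, with a median of -0.03, and 2 were higher after length adjustment. Serpina3f and Serpina3g, serine protease inhibitors that start 1.82 and 1.84 Mb from the start of Lgmn, were 9.93-fold (6.72 to 16.5) and 6.57-fold (4.65 to 10.1) higher. They belong to a family of similar copies, and the summed counts of its 5 listed members were 6.17-fold higher.

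The most abundant transcripts were shared. Ftl1, Fth1, B2m, Ctss and Gpnmb, for ferritin chains, beta-2 microglobulin, cathepsin S and a lysosomal glycoprotein, took the 5 highest counts in both libraries. The log2 scaled counts of the libraries had a Pearson r of 0.955 across genes. Xist, a very long transcript, had a log2 ratio of 1.87 and of 0.28 after length adjustment. Of 6 nuclear-retained RNAs tested, 3 were at least 2-fold higher and 0 lower, and 1 and 1 after length adjustment. Of 26 mitochondrially encoded genes, 0 were listed in either library. Of the other genes with the largest ratios, Wdfy1 was 5.43-fold higher, and Spata13 and Spen were 7.79-fold and 5.40-fold higher. Spen has a long transcript, and its log2 ratio of 2.43 was 1.20 after length adjustment. Gt(ROSA)26Sor, the transcript of the Rosa26 locus, was 7.67-fold lower (6.49 to 9.25). Its log2 ratio of -2.94 was -2.30 with deposited FPKM. Fam177a had 505 and 2.39 counts and Evi2b 136 counts in the wild type library and no listing in the knockout library, but both share sequence or a locus with a neighbour. The sum with Fam177a2 was 1102 and 893 counts, and the sum with Evi2 780 and 1317, so these 2 genes are uncertain.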

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

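The length adjustment and length-matched random lists were chosen after the data were seen, and the other alternatives before. Genes at least 2-fold higher numbered 575 and lower 165. Totals gave 1036 and 107, and FPKM 936 and 102. The median shift of a gene's log2 ratio was 0.24 with either, and 10 and 11 of 39 list medians crossed 0. Minimums of 10, 200 and no counts gave 921 and 436, 273 and 67, and 1458 and 1531, since fewer or more genes entered. With no minimum, all 849 genes found only in the wild type file and 924 only in the knockout file were counted. Their median was 1 count in either file. After scaling, 1 wild type count alone made a gene at least 2-fold lower, while 1 knockout count alone did not make it 2-fold higher. The numbers with no minimum thus rest partly on single counts. Thresholds of 1.5-fold and 4-fold gave 1562 and 607, and 40 and 45, by construction. Length adjustment gave 203 higher and 180 lower. The Lgmn log2 ratio of -6.01 was -5.77 with totals, -5.76 with FPKM and -5.84 after length adjustment. DESeq2 size factors, median centring, both pseudocounts and thinning left these counts within 1.5 times and the Lgmn ratio inside its counting interval.

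The median of the NRF2 and oxidative stress list crossed 0, from 0.04 to -7.36e-05 with minimums of 10 and of 200 counts and to -0.034 with no minimum. Nuclear-retained RNAs went from 1.002 to -0.071 with no minimum. The genes entering the lists differed, and the cause was not tested further. Of 39 list percentiles, length adjustment moved 10 across the bounds and length-matched random lists 4. A minimum of 10 counts moved 4 and no minimum 5. A minimum of 200 counts moved 4, with fewer lists having a percentile. Evi2b aside, no named gene that passed 2-fold changed sign under any scaling, pseudocount, thinning or length adjustment run. No paired analysis was possible because each group has 1 library and the result comes from no test. Leaving out a replicate was not possible for the same reason. Genes near 50 counts have wide counting intervals, and variation between mice is not measured.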

Other observations

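The tests in this part, the families and Ifng were chosen after the values were seen, while the T and NK cell, matrix and fibroblast lists were fixed earlier. Bootstrap intervals come from 1000 redraws of the genes of a set, which are not independent replicates. They describe the spread among genes of these libraries and not variation between mice or libraries. The interferon-inducible GTPases went one way as a family. All 20 tested members had a log2 ratio above 0, 12 of them at least 2-fold higher in the knockout library, and 10 after length adjustment. Under total scaling each is higher by a further 0.24. Ifng, which encodes interferon gamma, had 10 counts in the wild type library and 63 in the knockout library, 5.03-fold higher (2.75 to 11.8). The cytotoxic granule genes Gzma, Gzmb, Prf1 and Nkg7 had a median log2 ratio of 0.63, with 0 of 4 past 2-fold. The granzymes Gzmd, Gzme and Gzmg, a cluster of similar copies, went the other way, with a median of -1.32 and of -0.99 after length adjustment.

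Long transcripts were higher in the knockout library, with a Spearman rho of 0.609 between log2 ratio and length over 9498 genes. GC content is argued against as the source, because the lowest correlation within 5 groups of the genes by GC content was 0.580 (bootstrap interval 0.544 to 0.612). Expression level is argued against in the same way, with a lowest correlation of 0.472 (0.432 to 0.508) within 5 groups by mean expression. The trend was positive in 34 of 36 fixed lists with at least 10 members. This follows from the trend across all genes and points to no cause. A difference in RNA integrity or library preparation may underlie the trend, but it cannot be told apart from the genotype with 1 library each. The genotype itself stays open and untested.

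Extracellular matrix and fibroblast genes were lower, 18 of 23 by at least 2-fold and 20 of 23 after length adjustment. The length trend is argued against as the source, because the median with it removed was -2.57 (bootstrap interval -2.65 to -2.10). A larger share of macrophages, which the pan-macrophage list goes with at a length-adjusted median of 0.24, would by itself lower every other cell type alike. The length-adjusted median of the T and NK cell list was higher than that of these genes by 3.51 (bootstrap interval 2.88 to 3.73). Genes of either set could pass the minimum through a single library, which can widen this gap. The gap argues only against such a share as the sole difference. A larger share of macrophages together with more T and NK cells, or more transcript per such cell, stays open. Fewer mesenchymal or carcinoma cells in the knockout culture may account for the pattern, and this cannot be told apart from less transcript per cell, since the fibroblast markers are themselves the pattern and Epcam, Krt8 and Krt18, which bear on epithelial carcinoma cells and not on mesenchymal ones, had too few counts, 8 in each library. Genotype and differences between single mice stay open as well.

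Interferon-inducible GTPases were higher, with a median log2 ratio of 1.08. The length trend is argued against as the whole source by a median of 0.998 with it removed (bootstrap interval 0.856 to 1.15). Reads split between similar copies are argued against by the ratio of their summed counts, 1.06 (counting interval 1.03 to 1.08), from 20027 to 48568 counts. More interferon gamma from a larger share of T and NK cells may contribute, as 11 of 13 markers of those cells were above 0 after length adjustment, but more cells cannot be told apart from more transcript per cell in bulk RNA. An effect of the genotype on macrophages stays open and untested.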
